A study of Mus musculus with 22 samples.

How the data were processed

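RNA was sequenced from cultured primary liver cells of chow-fed C57BL/6 mice: hepatocytes with or without deferoxamine (DFO, an iron chelator, 100 uM; 6 control and 6 DFO libraries) and hepatic stellate cells with or without iron (100 uM; 5 control and 5 iron libraries). Per the labels' protocols, cells were plated for 24 h and treated for 24 h before RNA was isolated with a Zymo micro-scale kit, and libraries were sequenced on an Illumina HiSeq instrument. The protocol text names a small RNA library kit and speaks of 4 biological replicates per group, whereas the labels list 6 and 5 libraries. Of the deposited values, 97.7% of hepatocyte counts and 97.7% of stellate cell counts fell on protein-coding genes and 0.207% and 0.387% on annotated small RNA genes (at most 0.923% in a hepatocyte library, and 4.73% in stellate cell library control 3 against at most 0.640% in the other 9), so the values were treated as gene-level RNA-seq. The labels do not say whether libraries of one group came from separate animals or cultures, and p-values therefore measure the spread between these libraries, which may be technical.

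The deposited counts are whole-number read counts per Ensembl gene and library, and the deposited FPKM values were computed by the authors from the same counts: in every value above 1 the FPKM lay within 1% of the count per kilobase of the exonic size column and per 1e6 counts of the library. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1 and the mm10 build were used. The counting program, annotation release and strand setting are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart, and genes with near-identical copies (Fth1 and Ftl1 with their processed pseudogenes, Hamp with Hamp2) carry uncertain counts. The deposited hepatocyte values cover 55401 genes and the stellate cell values 55573. Of these, 55141 and 55480 IDs occur in GENCODE M21, 54784 and 55267 with the same start and end, so coordinates are given as in the tables (mm10). Total counts ranged from 19342490 to 41839154 per hepatocyte library and from 12058226 to 32067635 per stellate cell library. No pair of libraries of a group agreed within sampling noise (chi-square over its degrees of freedom at least 3.44 in hepatocytes and 5.59 in stellate cells).

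Each cell type was fitted alone. The test planned for FPKM values was replaced, as laid down beforehand for tables that hold counts, by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM normalisation, filterByExpr), which kept 15660 hepatocyte and 15502 stellate cell genes; Benjamini-Hochberg adjusted p under 0.05 was the threshold. Log2 fold changes are given with the standard error that the test's F value implies, and levels as TMM-normalised CPM (counts scaled to 1e6 per library), mean ± SD over libraries. For a simulation, counts were drawn from the fitted means and dispersions with 200 genes changed, all with a mean of at least 5 CPM. Each gene was drawn independently, so shifts of a whole library, or of many genes together, were not simulated. The same test recovered 49 of 50 genes changed 1.5-fold and 50 of 50 changed 2-fold in the hepatocyte design (15660 genes). In the stellate cell design (15502 genes) it recovered 0 of 50 at 1.5-fold, 5 of 50 at 2-fold, 31 of 50 at 4-fold and 47 of 50 at 8-fold. Of the genes called, 7.87% (hepatocytes) and 3.49% (stellate cells) had not been changed.

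Lists of genes were fixed before the data were examined: iron handling, iron-sulphur cluster and haem synthesis, iron-dependent dioxygenases, HIF targets, pathways of carbon, lipid, bile acid and xenobiotic metabolism, hepatocyte identity, stress responses, NRF2 targets, ferroptosis, metallothioneins, lysosome, extracellular vesicles, cell cycle, p53 targets, ribosomal proteins, inflammation, interferon response, matrix, contractile, TGF-beta and YAP targets, metalloproteinases, quiescent stellate cell genes, and markers of 6 other kinds of cell (macrophages, sinusoidal endothelium, cholangiocytes, lymphocytes, erythroid and stellate cells). Each with 5 or more tested members was tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation of 0.01, two-sided), with an estimated correlation and fry as alternatives. Genes are named by a rule fixed beforehand: 7 iron genes whatever their values, the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap and whose mean FPKM reaches 5 in the higher group (predicted genes left out), and up to 4 members of smallest p from each list described; any other gene is said to be chosen after its values were seen. Some genes that this rule takes are not reported here, but remain in the counts and the tests of lists. GO biological process terms in the deposited tables were tested in the same way.

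Alternatives fixed beforehand were limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with FPKM of at least 0.5, no expression filter, a mean FPKM of at least 5, DESeq2 size factors, quantile normalisation, DESeq2 1.42.0, voom with quality weights, the replicate number as a block, an adjusted p under 0.01 and leaving out each library. Chosen after seeing the data were robust dispersions and a fit without stellate cell libraries control 3, iron 3 and iron 5, whose FPKM values sum to over 400000 (the "7 libraries" below). Same-numbered libraries were not treated as pairs. Single-value comparisons use exact permutation tests, two-sided. Intervals of shares are Wilson 95% intervals, which cover counting error only. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.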

Results

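Transcript levels were measured in 22 libraries of cultured mouse liver cells. Primary hepatocytes, the parenchymal cells of the liver, were compared with and without DFO, which binds iron and withdraws it from the cell (6 libraries each). Hepatic stellate cells, the vitamin A-storing pericytes that make collagen in liver fibrosis, were compared with and without added iron (5 libraries each). Total counts were 19342490 to 41839154 per hepatocyte library and 12058226 to 32067635 per stellate cell library.

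The first comparison asked how hepatocytes respond to iron removal. Transcripts of genes switched on by hypoxia-inducible factor (HIF), whose degradation depends on iron-containing prolyl hydroxylases, rose with DFO. Bnip3, a mitophagy receptor (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519, mm10), rose from 45.3 ± 2.25 to 632.6 ± 13.7 CPM (mean ± SD, n = 6 each), a log2 change of 3.80 ± 0.05 (SE; edgeR adjusted p = 4.67e-19). Egln3, itself a HIF prolyl hydroxylase (chromosome 12, 54178981 to 54203860), rose 19.2-fold, from 3.61 ± 0.43 to 68.8 ± 5.35 CPM. Of 29 cell cycle genes 27 fell and 1 rose, and of 25 cholesterol synthesis genes 19 fell and 2 rose, but with an estimated correlation neither list passed (adjusted p = 0.0901 and 0.0504). Over all genes, 4375 were higher and 4713 lower with DFO of 15660 tested, 723 and 568 of them by more than 2-fold, and the first principal component, with 62.5% of the variance, separated the groups. The groups did not overlap for 35.9% of tested genes, where chance gives 0.216%.

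**Figure D1:**
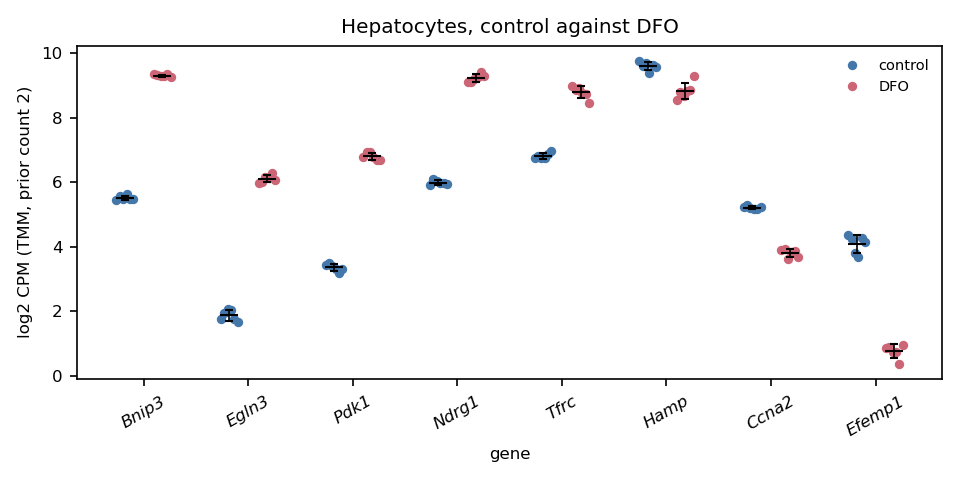
Log2 CPM of 8 genes (x axis) in each hepatocyte library (points; control blue, DFO red), with mean and SD as black bars. Bnip3, Egln3, Pdk1, Ndrg1 and Tfrc lie higher in all 6 DFO libraries than in all 6 controls, and Hamp, Ccna2 and Efemp1 lie lower.

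Of 28 tested HIF targets, 24 rose and 1 fell (median log2 change 1.97; camera adjusted p = 1.60e-16), and this list kept its call with an estimated correlation (adjusted p = 0.000285). Besides Bnip3 and Egln3 it held Ankrd37 (log2 change 5.25 ± 0.21), Pdk1, whose product inhibits pyruvate dehydrogenase (3.46 ± 0.07), and Ndrg1 (3.25 ± 0.06). The list of iron-dependent dioxygenases, which shares Egln1, Egln3, P4ha1, P4ha2 and Kdm3a with the HIF list, had 16 of 24 members higher and 1 lower (adjusted p = 3.26e-07, and 0.0901 with an estimated correlation). Its members of smallest p included Plod2 and P4ha1, collagen hydroxylases (2.75 ± 0.07 and 2.37 ± 0.06). Of 19 glycolysis genes 16 rose and 3 fell (median 1.56; adjusted p = 1.98e-08, and 0.183 with an estimated correlation). Pfkp rose by 2.92 ± 0.05, Pfkl by 2.78 ± 0.08, the lactate exporter Slc16a3 24.2-fold, and lactate dehydrogenase Ldha from 878.4 ± 77.2 to 3535 ± 351 CPM. Other large increases were those of Depp1 (3.12 ± 0.12) and the growth factor Pgf (2.92 ± 0.10).

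Among genes of iron handling, 11 of 31 rose and 8 fell, without a shift of the list (adjusted p = 0.733). Transferrin receptor Tfrc, which imports iron (chromosome 16, 32608920 to 32632794), rose from 112.8 ± 7.82 to 443.3 ± 52.8 CPM (adjusted p = 1.13e-12). The importer Slc11a2 rose by 0.33 ± 0.04. Hamp, which encodes the iron hormone hepcidin (chromosome 7, 30942368 to 30944032), fell from 783.2 ± 67.6 to 461.0 ± 85.5 CPM (adjusted p = 3.07e-06). Fth1 and Hmox1 rose by 0.35 ± 0.07 and 0.26 ± 0.07. Ferritin light chain Ftl1 rose by 0.22 ± 0.09 (adjusted p = 0.0358), and this call was absent without any 1 of controls 4, 5 and 6 or DFO 4, 5 and 6 (adjusted p from 0.0562 to 0.0871). It was also absent with limma on log2(FPKM + 1) (adjusted p = 0.0883), with limma on log2(FPKM + 0.1) (0.0874), with voom and quality weights (0.0868) and with the replicate block (0.111). Reads of Fth1, Ftl1 and Hamp can be divided by the counting with near-identical copies, so their values are uncertain. The exporter Slc40a1 did not pass (0.06 ± 0.04, adjusted p = 0.278). Of 25 iron-sulphur cluster and haem synthesis genes 3 rose and 11 fell (adjusted p = 0.0898). Of 8 metallothionein and zinc transport genes 4 rose and none fell (adjusted p = 0.0770).

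The cell cycle list fell, with 27 of 29 members lower and 1 higher (median −0.90; adjusted p = 1.89e-12, and 0.0901 with an estimated correlation). Cyclin Ccna2 fell from 37.0 ± 1.01 to 13.9 ± 1.24 CPM, and Plk1, Bub1b and Ccnb2 had log2 changes of −1.66 ± 0.07, −1.52 ± 0.07 and −1.67 ± 0.07. Of 18 p53 targets 13 rose and 4 fell (adjusted p = 0.0197, and 0.0901 with an estimated correlation), with Pmaip1 at 1.34 ± 0.08 and Gadd45a at 0.84 ± 0.05. Of 20 lysosome and autophagy genes 16 rose and none fell (adjusted p = 1.72e-06, and 0.274 with an estimated correlation), among them the autophagosome protein genes Gabarapl1 (0.87 ± 0.05) and Map1lc3b (0.70 ± 0.05).

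In lipid metabolism, 19 of 25 cholesterol synthesis genes fell and 2 rose (median −0.45; adjusted p = 5.40e-05, and 0.0504 with an estimated correlation). The isomerase Idi1 had a log2 change of −1.24 ± 0.09, while Insig1, which holds back the transcription factors of the pathway, rose by 0.76 ± 0.05. Lipogenesis and lipid storage genes went both ways (8 higher, 13 lower of 28; adjusted p = 0.367): Elovl6 (−1.54 ± 0.07), Acaca (−1.07 ± 0.07) and fatty acid synthase Fasn (−0.84 ± 0.07) fell and Lpin1 rose by 0.83 ± 0.07. Of 18 TCA cycle genes 10 fell and 1 rose (adjusted p = 0.0354, 0.656 with an estimated correlation and 0.0565 with the replicate block), with Idh3a at −0.60 ± 0.05 and the anaplerotic enzyme Pcx at 0.58 ± 0.06. In the gluconeogenesis and insulin signalling list 8 of 18 rose and 4 fell (adjusted p = 0.584). Its Igfbp1 rose by 1.49 ± 0.08 and Foxo1 by 0.85 ± 0.06, and Pck2 and the glucagon receptor Gcgr fell (−1.05 ± 0.07 and −0.95 ± 0.09).

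Genes of interferon response fell in 15 of 18 cases (adjusted p = 0.00619, and 0.655 with an estimated correlation), with Ifit1 falling from 85.9 ± 34.5 to 34.6 ± 1.81 CPM. Of 14 contractile and cytoskeletal genes 9 fell and 1 rose (adjusted p = 0.0197, and 0.0901 with an estimated correlation), and of 18 TGF-beta and YAP targets 11 fell and 5 rose (adjusted p = 0.0375, and 0.278 with an estimated correlation). The call of the TGF-beta and YAP list was also absent with limma on log2(FPKM + 1) (adjusted p = 0.0679). Cnn2 and Tagln, which bind actin, had log2 changes of −1.54 ± 0.06 and −1.74 ± 0.11, and Ltbp2 and the receptor Axl had −2.38 ± 0.10 and −1.90 ± 0.06. Among the 10 leading decreases were those of the matrix protein gene Efemp1 (−3.39 ± 0.13), Fscn1 (−2.56 ± 0.08), AA414768, Eprn, Serpinb6b, Gimd1, Apom and Selenbp2 (−1.90 ± 0.09). Macrophage markers were higher beside these decreases, with 11 of 14 up and Cd14 down (adjusted p = 0.00311, and 0.536 with an estimated correlation), and Cd68 rose by 1.34 ± 0.07.

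The other lists did not pass in hepatocytes. Higher and lower members numbered 1 and 14 of 42 for the respiratory chain, 5 and 10 of 27 for fatty acid oxidation, 2 and 7 of 15 for bile acids, 9 and 9 of 23 for xenobiotic metabolism, and 10 and 10 of 26 for hepatocyte identity. They numbered 8 and 13 of 26 for the integrated stress response, 5 and 4 of 18 for the unfolded protein response, 7 and 9 of 26 for NRF2 targets, 4 and 7 of 14 for ferroptosis, and 10 and 3 of 19 for vesicle machinery. For ribosomal proteins they were 10 and 3 of 34, for inflammation 8 and 9 of 23, for matrix 2 and 8 of 21, for metalloproteinases 4 and 5 of 12, for quiescent stellate cell genes 6 and 1 of 8, for endothelial markers 4 and 1 of 14, for cholangiocyte markers 2 and 3 of 6, and for stellate cell markers 3 and 1 of 8. Both tested lymphocyte markers (2) were higher and the 1 tested erythroid marker did not pass. The median, the mean and the test did not share a sign for hepatocyte identity, the unfolded protein response, ferroptosis and metalloproteinases. Adjusted over the list alone, the HIF, glycolysis, cholesterol and cell cycle counts were the same as over all genes. The camera calls other than that of the HIF list rest on the preset correlation.

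The second comparison asked how stellate cells respond to added iron. Macrophage and Kupffer cell markers (Kupffer cells are the resident macrophages of the liver) were higher in all 5 iron libraries than in all 5 controls. Clec4f, a lectin used to mark Kupffer cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), went from 0.33 ± 0.19 to 88.9 ± 26.8 CPM (mean ± SD, n = 5 each; log2 change 7.97 ± 0.51, edgeR adjusted p = 1.23e-05), and Cd5l from 5.69 ± 1.99 to 595.2 ± 109.5 CPM. Of 28 matrix and fibrogenesis genes 11 fell and 2 rose (camera adjusted p = 0.000102, and 0.511 with an estimated correlation). Elastin Eln fell from 55.8 ± 23.7 to 1.70 ± 1.03 CPM (adjusted p = 0.00147), and the collagen cross-linking enzyme Lox from 4189 ± 661 to 904.1 ± 430.2 CPM (adjusted p = 0.00563). Of 15502 tested genes 628 were higher and 523 lower with iron, and the groups did not overlap for 21.9% of genes, where chance gives 0.794%. All these changes are those of whole cultures. The mixture of cells may differ between the groups, so no change can be assigned to the stellate cells alone.

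Libraries control 3, iron 3 and iron 5 stood apart from the rest. Their FPKM values summed to 483000, 424253 and 503333, against 297988 to 333718 in the other 7, and iron 5 had counts for 12535 genes, against 18753 or more elsewhere. The mean exonic length behind a count was 7.23 kb in control 3, 4.27 kb in iron 3 and 4.02 kb in iron 5, and 5.16 to 5.69 kb in the other 7. Annotated small RNA genes held 4.73% of the counts of control 3 and 0.640% of those of iron 5, against 0.0527% to 0.113% in the other 8. In the 7 libraries 2988 genes were higher and 3224 lower, and 1150 of the 1151 genes called with all libraries were called in the same direction. Without iron 5 alone the counts were 1186 higher and 1276 lower. They were 343 and 262 without control 1, 356 and 263 without control 2, 366 and 272 without control 4, 389 and 296 without control 5, 441 and 329 without iron 3, and 417 and 269 without iron 4. With the replicate number as a block, 36 of 56 called genes of the naming rule did not pass (adjusted p from 0.0520 to 0.246), among them Eln (0.0640), Lox (0.0682) and Hamp (0.140), at log2 changes of 0.837 to 1.22 times those without the block.

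**Figure D2:**
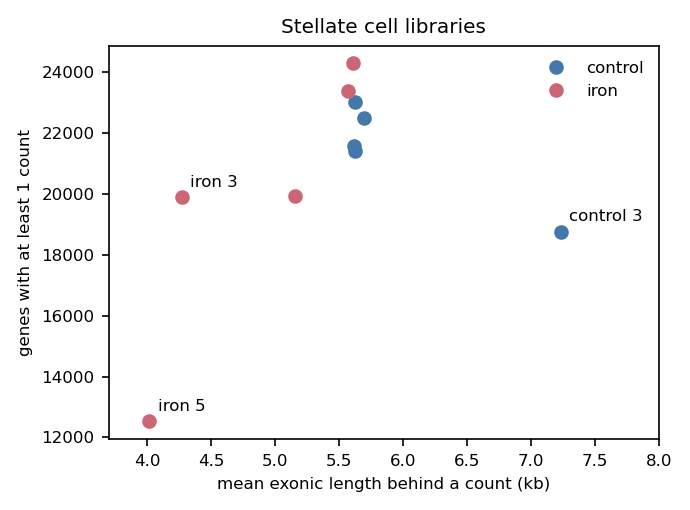
Genes with at least 1 count (y axis) against the mean exonic length in kb behind a count (x axis) for the 10 stellate cell libraries (points; control blue, iron red). Control 3, iron 3 and iron 5, which are labelled, lie outside the 5.16 to 5.69 kb spanned by the other 7.

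All 14 tested macrophage and Kupffer cell markers rose (median log2 change 4.56; adjusted p = 1.34e-24), and this was the list that kept its call with an estimated correlation (adjusted p = 0.00706, but 0.133 in the 7 libraries, where all 14 rose again). C1qa, Vsig4 and Marco rose by 7.62 ± 0.68, 7.17 ± 0.59 and 7.19 ± 0.65, C1qc and C1qb, the other chains of complement C1q, by 5.95 ± 0.34 and 5.83 ± 0.81, and lysozyme Lyz2 by 2.60 ± 0.21. Aif1, Ccl6 and Wfdc17 were also among the 10 leading increases (5.88 ± 0.92, 5.44 ± 0.29 and 5.27 ± 0.50). The log2 changes of C1qa, Marco, C1qb, Aif1 and Wfdc17 were smaller in the 7 libraries (6.74, 6.45, 4.86, 4.09 and 4.29), and that of Stab2 was larger (3.68). Of 14 endothelial markers 6 rose (adjusted p = 1.28e-05, and 0.0528 with an estimated correlation), among them Fcgr2b (3.25 ± 0.34), Stab2 (2.97 ± 0.46), Gpr182 (2.84 ± 0.43) and Pecam1 (1.76 ± 0.20). In the 7 libraries 13 rose and 1 fell.

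**Figure D3:**
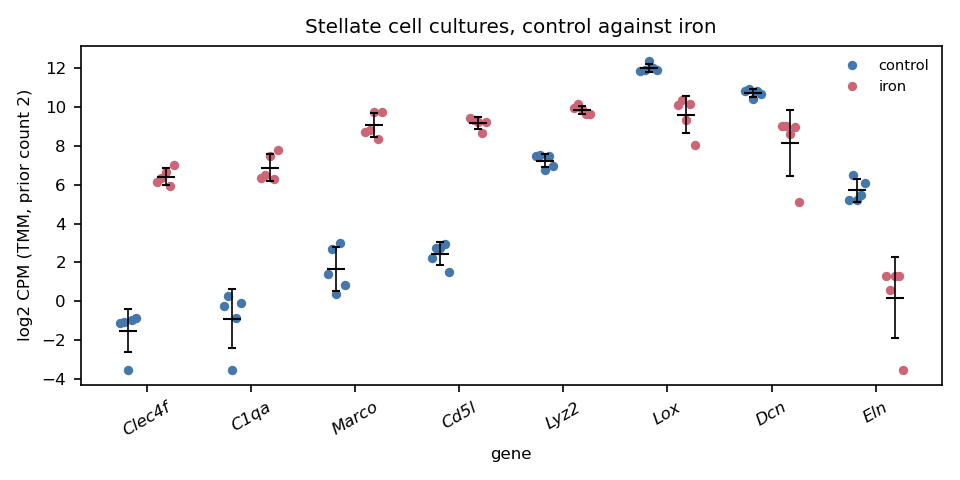
Log2 CPM of 8 genes (x axis) in each stellate cell library (points; control blue, iron red), with mean and SD as black bars. Clec4f, C1qa, Marco, Cd5l and Lyz2 lie higher in all 5 iron libraries than in all 5 controls, and Lox, Dcn and Eln lie lower.

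Among the 28 matrix and fibrogenesis genes 18 fell and 4 rose in the 7 libraries (adjusted p = 7.38e-05, and 0.142 with an estimated correlation). Besides Eln and Lox, the proteoglycan gene Dcn fell from 1714 ± 227 to 398.7 ± 211.0 CPM (adjusted p = 0.0404) and Col6a2 had a log2 change of −0.96 ± 0.16. Spp1, which macrophages also express, rose by 2.25 ± 0.38. Of 12 stellate cell markers 4 fell (adjusted p = 0.00394, and 0.511 with an estimated correlation), here Reln (−2.54 ± 0.40), Pdgfrb (−0.92 ± 0.19), Lrat (−3.02 ± 0.71) and Dcn, and in the 7 libraries 9 fell. This list shares 6 members with the matrix list. The falls of both lists cannot be told apart from a lower share of stellate cells in the iron cultures. The call of Dcn was absent when any 1 library other than iron 5 was left out (adjusted p from 0.0590 to 0.0987) and with limma on log2(FPKM + 0.1) (0.0651), and that of Lrat without any 1 control, iron 3 or iron 4 (0.0566 to 0.0760). In the 7 libraries the log2 changes of Dcn, Lrat, Reln and Abca8a were −1.79, −2.35, −1.82 and −2.75. The contractile list went up, with 4 of 17 members higher (Cnn1, Actg2, Acta1 and Tpm2; adjusted p = 0.0222, and 0.458 with an estimated correlation). That call was absent in the 7 libraries (adjusted p = 0.204) and without iron 5 (adjusted p = 0.0733), although Cnn1 rose by 2.76 ± 0.31 with all libraries and by 2.13 in the 7. The call of Tpm2 was absent without any 1 control, iron 3 or iron 4 (adjusted p from 0.0539 to 0.0919) and with limma on log2(FPKM + 0.1) (0.0536). Other leading decreases were those of Myoc (−8.21 ± 0.82, 9 counts in the iron libraries together), Cyp2a5, Ccn5 (488.6 ± 121.5 to 32.1 ± 2.63 CPM), Ackr3, Abca8a, Prelp and complement C3 (−3.42 ± 0.22). The call of Abca8a was absent without control 1, control 2, iron 3 or iron 4 (adjusted p from 0.0511 to 0.0650).

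Of 29 cell cycle genes 15 rose (adjusted p = 3.08e-11, and 0.0528 with an estimated correlation), and all 29 rose in the 7 libraries. Rrm2 and Tk1, which supply nucleotides for DNA synthesis, rose by 1.08 ± 0.17 and 2.00 ± 0.31 (1.40 for Tk1 in the 7 libraries). Of 25 cholesterol synthesis genes 9 fell (median −1.02; adjusted p = 5.38e-07, and 0.0528 with an estimated correlation), and 23 fell in the 7 libraries. Insig1, Msmo1 and Cyp51 had log2 changes of −1.31 ± 0.15, −1.15 ± 0.18 and −1.02 ± 0.16. Of 24 lipogenesis genes 6 fell (adjusted p = 0.0222, and 0.135 with an estimated correlation), with Fads1 at −0.69 ± 0.14 and Gpam at −0.97 ± 0.22, and the call was absent without iron 1, iron 2 or iron 4 (adjusted p = 0.0566, 0.0627 and 0.0576). In the 7 libraries 13 of 25 lipogenesis genes fell and 3 rose (camera adjusted p = 0.00217, and 0.211 with an estimated correlation). The call of Gpam was absent without control 1, control 4, iron 3 or iron 4 (adjusted p from 0.0539 to 0.0663), and that of Fads1 with no expression filter (0.0557). Of 19 inflammatory genes 7 fell and 1 rose (adjusted p = 0.0109, and 0.580 with an estimated correlation), among them the chemokines Ccl2 (536.4 ± 181.0 to 141.4 ± 42.7 CPM), Ccl20 (−3.69 ± 0.69), Cxcl1 (−1.24 ± 0.23) and Cxcl10 (−3.29 ± 0.66), and the acute phase gene Lcn2 (−3.65 ± 0.77). The call of Lcn2 was absent without control 1 or iron 4 (adjusted p = 0.0511 and 0.0504). In the 7 libraries 15 of 21 inflammatory genes fell and 4 rose (camera adjusted p = 0.000288, and 0.202 with an estimated correlation). The median of this list was −0.95 with all libraries and −1.75 in the 7.

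The ribosomal protein and respiratory chain lists ranked high by camera (adjusted p = 1.21e-09 and 3.19e-07; with an estimated correlation, adjusted p = 0.580 for both), with 1 of 34 and 0 of 41 members past the threshold. Of the members of smallest p, Rpl5 rose by 1.19 ± 0.30, and Rpl27a and Ndufs8 were at 1.44 ± 0.41 and 1.51 ± 0.49 without passing. Rpl27a and Ndufs8 passed with DESeq2 (adjusted p = 0.00735 and 0.0197) and, at smaller log2 changes of 0.45 and 0.39, with voom and quality weights (0.00392 and 0.0262). In the 7 libraries Rpl27a and Ndufs8 passed at log2 changes of 0.48 and 0.43 (edgeR adjusted p = 0.00293 and 0.00467). The call of Rpl5 was absent without any 1 control, iron 3 or iron 4 (adjusted p from 0.0515 to 0.0971) and with no expression filter (0.0740). The list medians were 1.24 and 0.92 with all libraries and 0.28 and 0.13 in the 7, and library control 3, with 7.23 kb behind a count, lay lowest among the controls for both lists. In the 7 libraries 21 of 34 and 6 of 41 members were higher and 0 lower (camera adjusted p = 5.87e-05 and 0.0284, and 0.508 and 0.704 with an estimated correlation). Genes of hepatocyte identity, xenobiotic metabolism and bile acids also ranked low (adjusted p = 0.00961, 0.0109 and 0.0187, and 0.580, 0.580 and 0.135 with an estimated correlation), with 2 of 25, 1 of 13 and 2 of 6 lower and 1 hepatocyte identity gene higher. In the 7 libraries 21 of 26, 12 of 17 and 3 of 7 were lower, and 2 hepatocyte identity genes were higher. There the camera adjusted p values were 3.06e-06, 3.73e-05 and 0.0115 (0.142, 0.133 and 0.142 with an estimated correlation).

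Iron handling genes did not shift as a list (3 higher, 2 lower of 30; adjusted p = 0.316). Ferritin chain Fth1 was at 2991 ± 968 CPM without and 6204 ± 2842 CPM with iron (log2 change 1.05 ± 0.37, adjusted p = 0.108), and Ftl1 at 1.37 ± 0.58 (adjusted p = 0.156). Tfrc was at 0.46 ± 0.46 (adjusted p = 0.536), Hmox1 at −0.59 ± 0.28 (adjusted p = 0.196), and Slc11a2 and Slc40a1 at −0.15 ± 0.19 and 0.07 ± 0.42. Hamp was at 0.47 ± 0.34 CPM in the controls and 10.5 ± 14.1 CPM with iron (adjusted p = 0.0120), a level far below that of hepatocytes. In the 7 libraries Tfrc rose by 1.01 (adjusted p = 2.15e-06), Fth1 rose by 0.27 (adjusted p = 0.00651), Hmox1 fell by 0.60 (adjusted p = 1.03e-05), and Ftl1 turned to −0.22 (adjusted p = 0.0442). There Slc40a1 rose by 0.59 (adjusted p = 0.00195) and Hamp by 2.75 (adjusted p = 0.000147), against 4.45 ± 0.88 for Hamp with all libraries. Without iron 5 alone Tfrc passed as well (0.74, adjusted p = 0.0312). With voom and quality weights on all 10 libraries Tfrc, Slc40a1, Fth1 and Hmox1 passed at log2 changes of 1.02, 0.64, 0.28 and −0.63 (adjusted p = 1.50e-06, 0.000312, 0.0376 and 3.21e-06), and with DESeq2 Fth1 passed at 1.06 (0.0338).

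Iron-dependent dioxygenases (0 higher, 2 lower of 26) and interferon genes (1 and 2 of 17) ranked low by camera and the integrated stress response (3 and 1 of 25) high (adjusted p = 0.0484, 0.0463 and 0.0424, each 0.580 with an estimated correlation). The first call was absent without control 3 or any 1 of iron 1 to 4 (adjusted p from 0.0566 to 0.0863), the second without control 2, control 4, iron 1, iron 2 or iron 4 (0.0539 to 0.0939), and the third without control 2, control 3, iron 3 or iron 5 (0.0581 to 0.174). In the 7 libraries the stress response list had a median of −0.07 (adjusted p = 0.773). With the replicate block the dioxygenase and stress response lists did not pass (adjusted p = 0.0598 and 0.0565), nor did the stress response list with limma on log2(FPKM + 1) (0.0636). NRF2 targets did not pass with all libraries (1 higher, 5 lower of 26; adjusted p = 0.0646), with Srxn1 at −0.73 ± 0.15 and the peroxidase Gpx1 at 1.99 ± 0.47. In the 7, however, 18 of the 26 fell and 4 rose (adjusted p = 0.000158, and 0.303 with an estimated correlation), and Gpx1 was at 0.94. The call of Srxn1 was absent without control 1, 2, 4 or 5 or iron 4 (adjusted p from 0.0507 to 0.0630) or with no expression filter (0.0688), and that of Gpx1 without control 1, 2, 4 or 5 or iron 3 (0.0562 to 0.0726). Higher and lower members were 0 and 0 of 25 for iron-sulphur cluster and haem synthesis, 1 and 2 of 28 for HIF targets, 3 and 1 of 18 for glycolysis, 0 and 0 of 18 for the TCA cycle, 0 and 3 of 24 for fatty acid oxidation, and 0 and 0 of 17 for gluconeogenesis and insulin signalling. They were 0 and 2 of 18 for the unfolded protein response, 0 and 1 of 14 for ferroptosis, 0 and 0 of 6 for metallothioneins, 1 and 0 of 20 for lysosome, 0 and 1 of 20 for vesicle machinery, 0 and 1 of 18 for p53 targets, 0 and 0 of 18 for TGF-beta and YAP targets, 3 and 3 of 14 for metalloproteinases, and 1 and 2 of 18 for quiescent stellate cell genes, none past the list threshold with all libraries. Of these, 6 lists ranked low in the 7 libraries, none with an estimated correlation (adjusted p from 0.142 to 0.358): lysosome (15 lower, 2 higher of 20; adjusted p = 0.000160), the unfolded protein response (10 lower of 18; 0.000614), fatty acid oxidation (12 lower, 1 higher of 25; 0.00477), quiescent stellate cell genes (11 lower, 2 higher of 18; 0.00664), vesicle machinery (11 lower, 2 higher of 20; 0.0183) and metallothioneins (4 lower of 6; 0.0304). Of cholangiocyte and lymphocyte markers 2 of 4 and 1 of 1 were higher, and no erythroid marker was tested. The median, the mean and the test did not share a sign for ferroptosis and metalloproteinases. Adjusted over the list alone, 20 cell cycle genes and 24 ribosomal protein genes were higher and 14 cholesterol synthesis genes lower.

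The third comparison set the changes with iron removal in hepatocytes beside those with iron addition in stellate cells. Over the 13922 genes tested in both, which are not independent replicates, no correlation of the log2 changes beyond its error was found (Pearson r = 0.0048, jackknife SE 0.0680; Spearman rho = −0.0508). Genes higher in both numbered 200, against 154.3 from independent lists (Fisher's exact test, two-sided p = 1.62e-05), and genes higher with DFO and lower with iron 151, against 121.0 (p = 0.0016). By the same exact test, genes lower with DFO and higher with iron numbered 208, against 174.8 (p = 0.00242), and genes lower in both 154, against 137.1 (p = 0.0838). In the fit with 7 stellate cell libraries the correlation was near 0 as well (Pearson r = 0.0489, Spearman rho = −0.0424), while by the same exact test the counts exceeded those of independent lists in the opposite directions: 1026 genes were higher with DFO and lower with iron, against 808.0 (p = 3.32e-23), and 1095 lower with DFO and higher with iron, against 806.4 (p = 4.33e-40), while 687 were higher in both, against 718.3 (p = 0.133), and 892 lower in both, against 907.2 (p = 0.502). The exact test takes genes as independent, which they are not, so its p-values do not measure the spread between libraries. With all 10 stellate cell libraries the counts lay above those of independent lists in every pair of directions, so no preferred direction is read from them. The cell cycle list went down with DFO and up with iron, and the cholesterol synthesis list went down in both. With an estimated correlation none of these 4 calls was kept (cell cycle adjusted p = 0.0901 and 0.0528, cholesterol synthesis 0.0504 and 0.0528).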

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

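All tests in this part were chosen after the result was seen, and the rule that gave no verdict on stellate cell markers under 5 CPM was added after their value was seen. A library is named here where its gap to the nearest library of its group, divided by the range of the group, exceeded Dixon's 95% critical value. Of 434 groups of values, 97 did so, where chance gives 21.7. Most of the 97 came from stellate cell libraries control 3 and iron 5. The number that chance gives was not worked out for hepatocytes alone, so no excess is read from their values.

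Macrophage markers were higher in the iron-treated stellate cell cultures, with Lyz2, Cd5l and Marco at 935.3, 595.2 and 583.3 CPM. A lower share of stellate cells that raises the markers of every other cell type alike is argued against by the mean log2 change of the macrophage list, which exceeded that of the hepatocyte identity list by 5.92 (exact permutation, p = 0.00794, the smallest possible). A larger share of a single macrophage population of fixed make-up remains open. The mean log2 change of 7 Kupffer-restricted members (7.05) exceeded that of 4 leukocyte-restricted members (2.54) by 4.52, but the 2 sets were formed after the values were seen and the 7 are the members of largest rise, so this difference decides nothing. A separate preparation of the iron-treated cultures that carried more Kupffer cells remains open: 5 of 5 iron libraries lay above every control, and the labels do not say which cultures shared a preparation, so it cannot be told apart from an effect of iron on the cells. No sort or gate that would remove macrophages is given in the sources used here. For the other changes in these cultures, too, a separate preparation cannot be told apart from an effect of iron.

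Stellate cell libraries control 3, iron 3 and iron 5 stood apart. Lower depth as a cause shared by the 3 is argued against: iron 3 had 22448392 counts, more than iron 4, which is among the 7 others, with 14639862. Control 3 and iron 5 did have the fewest counts (13475562 and 12058226). In 1 random thinning to the depth of the shallowest library the lowest of the 7 others had 19068 genes detected and the highest of the 3 had 18903. A number of genes detected does not bear on the FPKM sum or the exonic length. A single shift in gene length shared by the 3 is argued against by a mean of 7.23 kb behind a count in control 3 and 4.02 kb in iron 5, on either side of the 5.16 to 5.69 kb of the others. In iron 5, 988 genes had no count although their median in the other iron libraries reached 5 CPM, while the 7 others thinned to its depth had 0 such genes, and few RNA molecules entering that library may account for this. No biological explanation was tested.

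Contractile and TGF-beta or YAP target genes were lower with DFO in the hepatocyte cultures. Fewer non-parenchymal cells of every type would lower the macrophage and endothelial lists, but their mean log2 change was 0.42 (0.415 before rounding, exact permutation, p = 0.00217, the smallest possible). This argues against it only weakly. The rule of 5 CPM was not applied to these lists, the endothelial list did not pass camera (adjusted p = 0.187), and the macrophage marker Cd14 fell. Fewer stellate cells remain open: the mean log2 change of stellate cell markers exceeded that of contractile genes by 0.78 (exact permutation, p = 0.0217), but the median marker was at 1.83 CPM, too near the floor to decide. An effect of DFO on the hepatocytes remains open as well and was not tested apart.

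In hepatocytes the following stood apart, each with its gap as a share of the range. Library DFO 6 lay below the rest of its group in the number of genes detected 0.654 and iron-dependent dioxygenases 0.652. Library control 6 lay below the rest of its group in HIF target genes 0.711 and xenobiotic metabolism 0.67. Library DFO 3 lay below the rest of its group in cell cycle 0.682. Library DFO 1 lay above the rest of its group in extracellular matrix and fibrogenesis 0.656, quiescent stellate cell genes 0.746 and stellate cell markers 0.644. Library control 1 lay above the rest of its group in cholangiocyte markers 0.662. Library control 4 lay above the rest of its group in Fth1 0.678. Library control 4 lay below the rest of its group in Serpinb6b 0.64. Library DFO 5 lay below the rest of its group in Gimd1 0.637. Library control 3 lay above the rest of its group in Selenbp2 0.668. Library control 2 lay below the rest of its group in Egln1 0.904. Library DFO 5 lay above the rest of its group in Adgre1 0.744. Library DFO 6 lay below the rest of its group in Ltbp2 0.666 and Lpin1 0.685.

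In stellate cells most values came from control 3 (49) and iron 5 (30), each with its gap as a share of the range. Library control 3 lay above the rest of its group in the sum of FPKM 0.951, the share of the top 50 genes 0.979, iron-dependent dioxygenases 0.889 and extracellular matrix and fibrogenesis 0.762. Library control 3 lay below the rest of its group in the mitochondrial share 0.871, iron-sulphur cluster and haem synthesis 0.894, HIF target genes 0.759, glycolysis 0.901, respiratory chain 0.945, TCA cycle 0.946, fatty acid oxidation and PPARalpha targets 0.897, integrated stress response 0.743, unfolded protein response of the ER 0.908, NRF2 targets and antioxidant enzymes 0.721, ferroptosis 0.852, lysosome and autophagy 0.824, extracellular vesicle machinery 0.718, p53 targets 0.77, ribosomal proteins 0.954 and contractile and cytoskeletal genes 0.875. Library iron 5 lay below the rest of its group in iron handling 0.915, iron-dependent dioxygenases 0.735, HIF target genes 0.814, cholesterol synthesis 0.915, fatty acid oxidation and PPARalpha targets 0.904, gluconeogenesis and insulin signalling 0.897, bile acid synthesis and transport 0.758, unfolded protein response of the ER 0.842, ferroptosis 0.774, extracellular vesicle machinery 0.929, cell cycle 0.749, p53 targets 0.856, inflammatory cytokines and acute phase 0.832, interferon response 0.779, TGF-beta and YAP target genes 0.718, matrix metalloproteinases 0.818, quiescent stellate cell genes 0.802 and stellate cell markers 0.837. Library control 3 lay above the rest of its group in Tfrc 0.809, Slc40a1 0.715, Prelp 0.863, C3 0.863, Lox 0.715, Reln 0.904, Pdgfrb 0.744, Fads1 0.811 and Gpam 0.879. Library iron 5 lay below the rest of its group in Tfrc 0.748, Hmox1 0.736, Eln 0.852, Ccl20 0.802, Spp1 0.875, Lrat 0.796, Dcn 0.891, Me1 0.826, Ccl2 0.718 and Cxcl10 0.851. Library control 3 lay below the rest of its group in Fth1 0.89, Ftl1 0.883, Hmox1 0.841, Clec4f 0.902, C1qb 0.733, Ccn5 0.886, Cdc20 0.807, Rpl5 0.781, Rpl27a 0.837, Rpl10a 0.815, Rpl14 0.93, Ndufs8 0.926, Ndufa5 0.96, Ndufa10 0.826, Atp5c1 0.885, Actg2 0.782, Tpm2 0.889, Ccl2 0.79, Cxcl1 0.766 and Gpx1 0.874. Library iron 1 lay above the rest of its group in Myoc 0.742. Library iron 5 lay above the rest of its group in Cyp51 0.771 and Fads2 0.753.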

How the results depend on the processing

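The fits with 7 libraries and with robust dispersions were chosen after seeing the data. In hepatocytes the counts of genes stayed within 1.5 times of 4375 and 4713 except among genes with a mean FPKM of at least 5 (2414 higher, 2360 lower; fewer genes tested). With limma on log2(FPKM + 1) they were less even, at 3154 and 4791 (39.7% of calls higher, against 48.1%; median log2 change of all genes −0.0454). They ranged from 4158 to 4665 and from 4491 to 5037 when 1 library was left out. Of 12 lists, 1 passed with an estimated correlation. With fry 24 of all lists passed, but fry does not compare a list with other genes. Genes higher with iron in stellate cells numbered 409 with a mean FPKM of at least 5, 1635 with DESeq2, 3057 with voom and quality weights, 2988 in the 7 libraries and 268 at an adjusted p under 0.01. Genes lower numbered 337 with no filter, 839 with quantile normalisation, 1289 with DESeq2, 3260 with voom and quality weights, 3224 in the 7 libraries and 171 at an adjusted p under 0.01. With 1 library left out they ranged from 343 (control 1) to 1186 (iron 5) and from 262 (control 1) to 1276 (iron 5). Of 17 stellate cell lists, 1 passed with an estimated correlation. With fry 10 lists passed, 9 of them among the 17. The stress response list reversed in the 7 libraries (adjusted p = 0.773). Slc40a1, which did not pass, turned to −0.16 and −0.20 with limma on log2(FPKM + 1) and log2(FPKM + 0.1) and to −0.10 with quantile normalisation, and ranged from −0.17 to 0.34 with 1 library left out. Ftl1 turned to −0.23 with voom and to −0.22 in the 7 libraries. The correlation of fold changes, near 0, was −0.05 with limma on log2(FPKM + 1) (−0.0478) and by rank (−0.0508), and ranged from −0.0465 to 0.0348 with 1 library left out. Apart from fits with fewer genes or libraries, the cause was not tested. At the spread of all 10 stellate cell libraries 5 of 50 simulated 2-fold changes were recovered, and 50 of 50 in the 7.

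With the replicate number as a block, 107 genes were higher and 68 lower with iron, and Slc40a1 turned to −0.18. Same-numbered libraries did not pair: their deviations from the group means correlated at −0.245 to −0.00274 in hepatocytes and −0.32 to 0.12 in stellate cells, so the numbers were not read as pairs and the lower counts of this paired fit are not read as a weaker effect.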

Other observations

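The tests of splits and of Tfrc in this part, and the fit with 7 libraries, were chosen after the result was seen. Among GO biological process terms tested with camera in hepatocytes (626 terms of 20 to 300 genes), 11 ranked high and 11 low with DFO, and 0 passed with an estimated correlation. Autophagosome assembly ranked high (16 of 26 genes higher, 2 lower; adjusted p = 0.00269, and 0.510 with an estimated correlation). So did the cellular response to interferon-gamma (30 of 52 genes higher, 12 lower, adjusted p = 0.0384, and 0.510 with an estimated correlation). Most genes of the interferon list fell, but which genes carry the rise of this term was not examined. The term is therefore not read as an interferon-gamma response. Ribosome biogenesis (28 of 48 lower, 1 higher; adjusted p = 0.00754) and tRNA processing (25 of 53 lower, 2 higher; adjusted p = 0.0113) ranked low (adjusted p = 0.677 and 0.637 with an estimated correlation).

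In all 10 stellate cell libraries (648 terms) 26 terms ranked high and 10 low with iron, 0 of them with an estimated correlation. Viral transcription ranked first (adjusted p = 2.26e-12, and 0.999 with an estimated correlation), although only 2 of its 105 genes were higher on their own. Terms of translation ranked next, and no viral process is read from it. The median log2 change of viral transcription was 1.14 with all libraries and 0.24 in the 7, where 26 of 109 genes were higher and 0 lower. With the 7 libraries alone (674 terms) 32 terms ranked high and 16 low, 0 of them with an estimated correlation. The genes of mRNA splicing via the spliceosome ranked high (36 of 74 higher, 1 lower; adjusted p = 1.60e-05). Glutathione metabolism (23 of 36 lower, 2 higher; adjusted p = 7.85e-06) and fatty acid beta-oxidation (16 of 32 lower; adjusted p = 0.00493) ranked low (adjusted p = 0.777 with an estimated correlation for all of these).

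A fall of the Tfrc transcript was the change that iron uptake in the cultures as a whole would give. With all 10 libraries the log2 change was 0.46 ± 0.46 (adjusted p = 0.536), which does not decide it. In the 19 other fits fixed beforehand it was above 0, from 0.14 to 1.02 (adjusted p from 1.50e-06 to 0.882), the highest with voom and quality weights on all 10 libraries. A log2 change of 1.01 (SE 0.0921) in the 7 libraries, chosen after the data were seen, argued against a fall of the transcript in the cultures as a whole. This value does not decide whether iron was taken up. Macrophage markers and cell cycle genes rose in the same libraries, and the mixture of cells may differ between the groups. A change in part of the cells remains possible and cannot be seen in bulk RNA.

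Other splits of the same libraries into groups of the same sizes were fitted. Libraries were taken as separate units, although the labels do not say whether they are. Such splits therefore say nothing on differences between cultures or preparations. In hepatocytes the real split gave 9088 genes, the highest of 100 drawn of 462 (1 as large), so a chance split of these libraries is unlikely to give as many genes. The highest of the other splits gave 4147 genes and differed from the real one by the exchange of control 6 and DFO 6. The number of hepatocyte lists is not decided by the splits: 13 of 100, the real one included, gave as many as the real 12, the highest other 13. Each of the others had more DFO libraries on 1 side, such as control 1 with every DFO library but DFO 2 (13 lists). They kept part of the difference with DFO, so they neither exclude chance nor show it. The number of lists says nothing about any single list. In stellate cells the real split gave 1151 genes and the highest other 1 (1 of 100 as large). It gave 17 lists, with the highest other also at 17 (3 of 100 as large). Counts of this size were thus rare among splits of these libraries, but for the lists the real split was not the only one to reach it. In the 7 libraries the real split gave 6212 genes and the highest other 1 (1 of 35 as large), so a chance split of these libraries is unlikely to give as many genes. The number of lists in the 7 libraries is not decided by the splits: 2 of 35 gave as many as the real 22, the highest other 23. The split with 23 lists differed from the real one by the move of control 5 to the iron group. It kept most of the difference with iron, so it neither excludes chance nor shows it.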
